A study of Mus musculus with 2 samples.

How the data were processed

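RNA of mouse retina at postnatal day 14, dissected with forceps, was amplified, labelled with Cy3 and hybridised to an Agilent mouse array, 1 array for WT and 1 for Mef2d KO, per the labels' protocols. The intensity values were made by the authors' scanner software, Agilent Feature Extraction 10.10.1.1, which subtracted background and detrended each spot's signal, per the file headers. The scanner intensities were not scaled between arrays. The deposited series table holds the same intensities multiplied by 1 constant per array (1.88 for WT and 1.76 for Mef2d KO). It is linear and not centred, its column medians are 155.1 and 136.6, and how the constants were chosen is not given in the sources used here. Every sample column of that table was used. Both arrays came from the same slide and scan.

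The main values were log2 of the processed signal minus each array's 75th percentile over the 59305 probe spots. That percentile was 807 on the WT array and 858 on the array labelled Mef2d KO. Control spots and spots flagged as outliers (106 and 126) were left out, and 12 probes were lost because every spot was so flagged on an array. Spots of 1 probe were averaged, which left 55669 probes. Of these, 27231 probes (48.9%) were named by matching their RefSeq accession without version to gene symbols of the GRCm38.p6 annotation, covering 20659 genes. The other 28438 probes, 16189 of them named only by a chromosome region, entered no gene count. The array design names the build mm9, so no position was taken from the annotation beyond the order of genes.

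Each gene was represented by its probe with the highest mean level. Counts used genes well above background on both arrays, by the scanner software's flag. A gene well above background on 1 array only, by all its probes, was given a bound, the bright array's value over the higher of the dim probe's own value and the lowest value well above background on the dim array. Gene list members needed a probe well above background on at least 1 array. A list's median was placed among 10000 random lists of distinct genes matched in 20 bins of mean level, and was called lower at or under percentile 2.5 and higher at or over 97.5. This describes these 2 arrays and is no test of the genotype. Random genes were matched on level only. Members of a list may vary together, as with the make-up of the tissue, which makes extreme percentiles easier to reach.

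The 27 lists, the designs and the rule for named genes were fixed before the data were examined. The rule took the MEF2 family and sex-linked transcripts, the 15 largest decreases and increases that also passed 2-fold with normexp background and quantile normalization, the 5 largest bounds of each direction, up to 4 members of each list with the largest differences, and a fixed set of retinal genes, some of which are not reported here. Unnamed models and clones were left out of it. Fscn2 and Guca1a are named in addition, to complete a count of 6, and Lgsn and Crygf to complete a count of 2. These 4 genes were chosen after their values were seen.

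Precision on single arrays is limited by their number. Over 389 probes with replicate spots, the median SD of the difference between spots was 0.082, 0.061 above a mean level of -3 and 0.39 at or below it. The scripts were tested on simulated data, 2 arrays made from the WT values with noise from the scanner error model. In that comparison of 16883 genes, all 50 genes at each of the simulated log2 changes -1.5, -3.0, 1.5 and 3.0 were recovered past 2-fold. Of 16683 unchanged genes, 53 passed it. The changed genes were drawn only from those far above the lowest signal well above background, so recovery of dim genes was not tested. The simulated noise held no trend with level between the arrays and no variation between animals or dissections. The 53 leave out calls from these sources and give no rate of false calls for the real arrays. Of 27 lists with no simulated effect 2 passed the percentile limits.

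Alternatives were median scaling, the 75th percentile over probes well above background on both arrays, quantile normalization, cyclic loess, normexp background (offset 50), the series table, the mean over a gene's probes, other filters on dim or saturated probes, and other list rules. The files hold no mean spot signal, so normexp was run on median spot and median background signals. Scripts used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.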

Results

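Gene expression in the mouse retina at postnatal day 14 was measured on 2 one-colour Agilent arrays. One array held RNA of wild-type (WT) retina and the other RNA of retina labelled Mef2d KO. Mef2d encodes a transcription factor of the MEF2 family, which acts in muscle and neurons. The comparison asks how expression in the retina differs when Mef2d is lost. With 1 array per group no difference has a replicate check and no p-value is given. On the WT array 75.5% of the probe spots were well above background, against 69.6% on the array labelled Mef2d KO, and no spot was saturated. Errors written as ± are those of the scanner software's error model for a difference between spots and leave out the variation between animals. All differences are log2 values of the array labelled Mef2d KO minus WT.

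Mef2d itself was not lower on the array labelled Mef2d KO. Its probes, both matched to the Mef2d transcript on chromosome 3, gave differences of 0.43 ± 0.20 and 0.14 ± 0.21. The first stood at a level of -0.091 in WT and 0.34 on the other array, relative to each array's 75th percentile. Where these probes lie relative to the deleted part of the gene is not given in the sources used here, so they check nothing by themselves. Every direction below is therefore that of the array labelled Mef2d KO. Among the other family members, Mef2c differed by -1.28 ± 0.23, and by -0.72 with normexp background correction. The single Mef2b probe differed by -0.45 ± 0.24 and the Mef2a probes by -0.23 and 0.011. Mef2b was dim, at a level of -3.67 in WT, and differed by -0.15 with cyclic loess and -0.20 with normexp background.

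The arrays differed in Xist, the RNA that coats the inactive X chromosome in female cells. Neither of its RefSeq-matched probes was well above background in WT, and by their bounds they were at least 52.6-fold and 26.9-fold higher on the array labelled Mef2d KO, with differences of 3.57 and 2.68 under normexp background. The Y-linked genes were read on both arrays, with differences of -0.36 for Eif2s3y, -0.46 for Ddx3y, -0.42 for Uty and -0.76 for Kdm5d. Kdm5d was the dimmest of them and differed by -0.34 with cyclic loess and -0.30 with normexp background. The labels used here do not give the sex or number of the animals. The Xist values argue against a like sex composition of the animals on these 2 arrays. Eif2s3y stood at a level of 2.30 on the array labelled Mef2d KO, so that array did not hold RNA of females alone. With 1 array per group no difference between the arrays can be assigned to genotype apart from sex. Of the 381 genes at least 2-fold apart, 13 lie on X or Y. Of all 16190 genes well above background on both arrays, 596 do.

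The largest decreases included genes of photoreceptor signalling and metabolism. Arr3, the cone arrestin that shuts off cone opsins, was 41.0-fold lower (difference -5.36 ± 0.20), and its other probe gave -8.23. Guca1b, a calcium sensor that activates guanylate cyclase in photoreceptors, was 36.3-fold lower (-5.18 ± 0.20). Hk2, a hexokinase at the entry of glycolysis, was 19.2-fold lower (-4.26 ± 0.21), and Pcdh15, a protocadherin of photoreceptors and hair cells, was 15.2-fold lower by its brightest probe (-3.93 ± 0.20), with -1.38 for its least affected probe. Pax7, a transcription factor of muscle progenitors and neural development, was 45.5-fold higher (5.51 ± 0.29, and 3.65 with normexp background).

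In all, 281 genes were at least 2-fold lower and 100 at least 2-fold higher among 16190 genes well above background on both arrays. Of these, 44 were at least 4-fold lower and 15 at least 4-fold higher. The share of lower genes among those 2-fold apart was 73.8%, and it was 53% with median scaling, 51.1% with quantile normalization, 51.3% with cyclic loess and 62.8% with normexp background. Median scaling moved the median of all genes to 0.17, so directions under it are read relative to that shift. Above a mean level of -3, 117 genes were at least 2-fold lower and 77 higher. At or below it, 164 were lower and 23 higher, and cyclic loess turned this into 51 and 68.

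**Figure D1:**
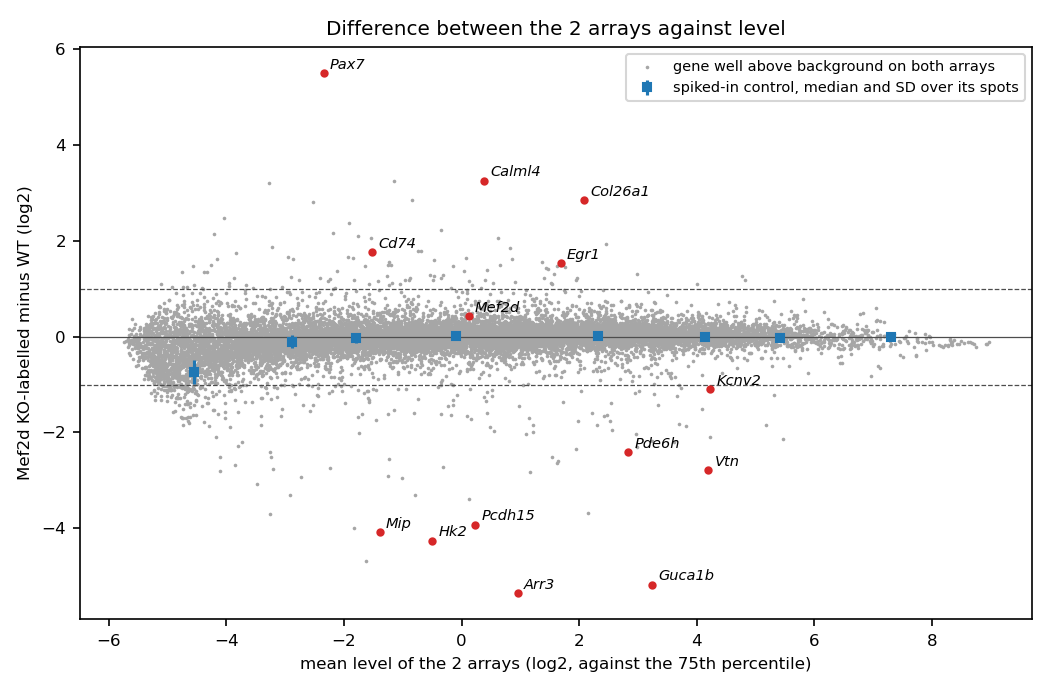
Each grey point is a gene well above background on both arrays, plotted by its mean level (log2, against each array's 75th percentile) and its log2 difference, array labelled Mef2d KO minus WT. Blue squares are spiked-in control transcripts with the SD over their spots. They lie near 0 above level -2 and at -0.74 near level -4.56, and dashed lines mark 2-fold. Dimmer controls, not well above background on the array labelled Mef2d KO, are not drawn.

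Other large decreases were in Jchain, the joining chain of secreted immunoglobulins (-4.69), Mip, the lens water channel (-4.09), and Sntg2, a syntrophin (-4.00). Ahrr, a repressor of the aryl hydrocarbon receptor, differed by -3.71, the small heat shock protein gene Hspb6 by -3.68 and the phospholipase A2 receptor gene Pla2r1 by -3.39. Cacna1s, a calcium channel subunit of muscle, was lower (-3.31), as were Tecrl (-3.08), the sulfotransferase gene Chst3 (-2.96), the muscle kinase gene Srpk3 (-2.93) and the crystallin gene Crygn (-2.91). Increases followed Pax7 in Calml4 (3.26), Tnfrsf13c, a B cell receptor for BAFF (3.25), Eps8l1 (3.21), the collagen gene Col26a1 (2.86), the mesoderm factor gene Mesp1 (2.85) and Padi6 (2.81). A second Tnfrsf13c probe had the opposite sign (-0.75). Insl6 (2.36), Syne3 (2.23), Zfp874a (2.17), the potassium channel gene Kcng1 (2.10), Tmc6 (2.06), the complement receptor gene Cr2 (2.06), Proser2 (1.94) and Slc45a3 (1.87) completed the 15 largest increases that also passed 2-fold with normexp background and quantile normalization, with unnamed models and clones left out. Normexp background brought several of these closer to 0, to -3.66 for Jchain, -3.27 for Mip, -3.15 for Sntg2, -2.15 for Ahrr, -2.005 for Srpk3 and -1.67 for Tecrl, and to 2.64 for Tnfrsf13c, 1.90 for Padi6, 1.73 for Eps8l1, 1.505 for Kcng1, 1.48 for Zfp874a and 1.02 for Slc45a3. Of the 45 genes past 2-fold with more than 1 probe, 6 had a probe of the opposite sign.

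Some genes were read on 1 array only, which gives a bound. Pdzph1 was at least 697-fold lower on the array labelled Mef2d KO (difference -7.36 with normexp background). Glb1l3 (at least 12.8-fold), H2al2a (at least 12-fold), Apobec2 (at least 11.1-fold) and Slc6a2, the noradrenaline transporter gene (at least 7.09-fold), were lower too, with differences of -1.82, -1.71, -1.91 and -1.05 under normexp background. Higher by such a bound were Soat2 (at least 3.30-fold), Ube2t (at least 2.93-fold), Mmp1b (at least 2.78-fold) and the hyaluronan synthase gene Has2 (at least 2.36-fold), but with normexp background these 4 differed by 0.37, 0.35, 0.46 and 0.27, within 2-fold. Of 1059 genes on 1 array only, 922 were on the WT array. This split does not by itself show lower expression, since a spiked-in control added in equal amount gave a like one. At level -6.26, it was well above background on 74.3% of its WT spots and 0% of those on the other array. Its median difference was -1.81. A bound of at least 2-fold was met by 176 lower and 6 higher genes. This balance turned to 32 lower and 57 higher with quantile normalization, and the counts were 96 and 8 with median scaling, 45 and 24 with cyclic loess and 7 and 1 with normexp background.

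Photoreceptor genes differed member by member. Of 15 measured cone genes, 2 were at least 2-fold lower and 13 within 2-fold. Pde6h, the inhibitory subunit of the cone phosphodiesterase, differed by -2.42 ± 0.20 besides Arr3. Kcne2 differed by -0.99, Opn1sw by -0.53, Opn1mw by -0.31 and Gnat2, the cone transducin, by -0.13 (0.047 with median scaling). The list median was -0.16, at percentile 0.04 of 10000 random lists matched on level. Of 38 measured genes used by rods and cones alike, 6 read on both arrays were at least 2-fold lower. None was 2-fold higher, and Glb1l3 was lower by its bound. The 6 were Guca1b, Pcdh15, Glb1l2 (-2.83), Fscn2, an actin bundler of photoreceptors (-2.72), Guca1a (-2.21), a paralog of Guca1b, and Kcnv2, a potassium channel subunit of photoreceptors (-1.10, and -0.93 with median scaling). This list's median of -0.14 lay below those of the 10000 random lists.

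Rod genes stayed within 2-fold except for 1 of 19, Esrrb, an orphan nuclear receptor of rods (-1.22). The rod transducin Gnat1 differed by -0.43, the rod arrestin Sag by -0.82 and Gngt1 by -0.62. Pde6b (0.38), Nr2e3 (0.37) and Samd7 (0.44) had positive differences. The list median of -0.061 stood at percentile 3.54 and was not called, but it was called lower at percentile 1.53 with 10 bins and at percentile 1.68 without genes of other lists (-0.091). Of 16 photoreceptor transcription factors, Esrrb and Mef2c were at least 2-fold lower and the other 14 within 2-fold, among them Crx (0.028), Otx2 (-0.029, and 0.15 with median scaling), Nrl (0.020), Prdm1 (0.78) and Pias3 (0.62). Their median of 0.024 stood at percentile 55.6. Of 34 photoreceptor synapse genes, Lrfn2 (-1.59) passed 2-fold, while Cabp4 differed by 0.33 and Cacna1f by 0.031. Their median of -0.044 stood at percentile 6.08. Of 40 connecting cilium genes 1, Pcdh15, passed 2-fold. Whrn, a scaffold of the periciliary membrane, differed by 0.72, Bbs5 by 0.41 and Arl3 by -0.45, and the median of 0.086 stood at percentile 98.6, or 0.052 at percentile 79.4 with normexp background.

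**Figure D2:**
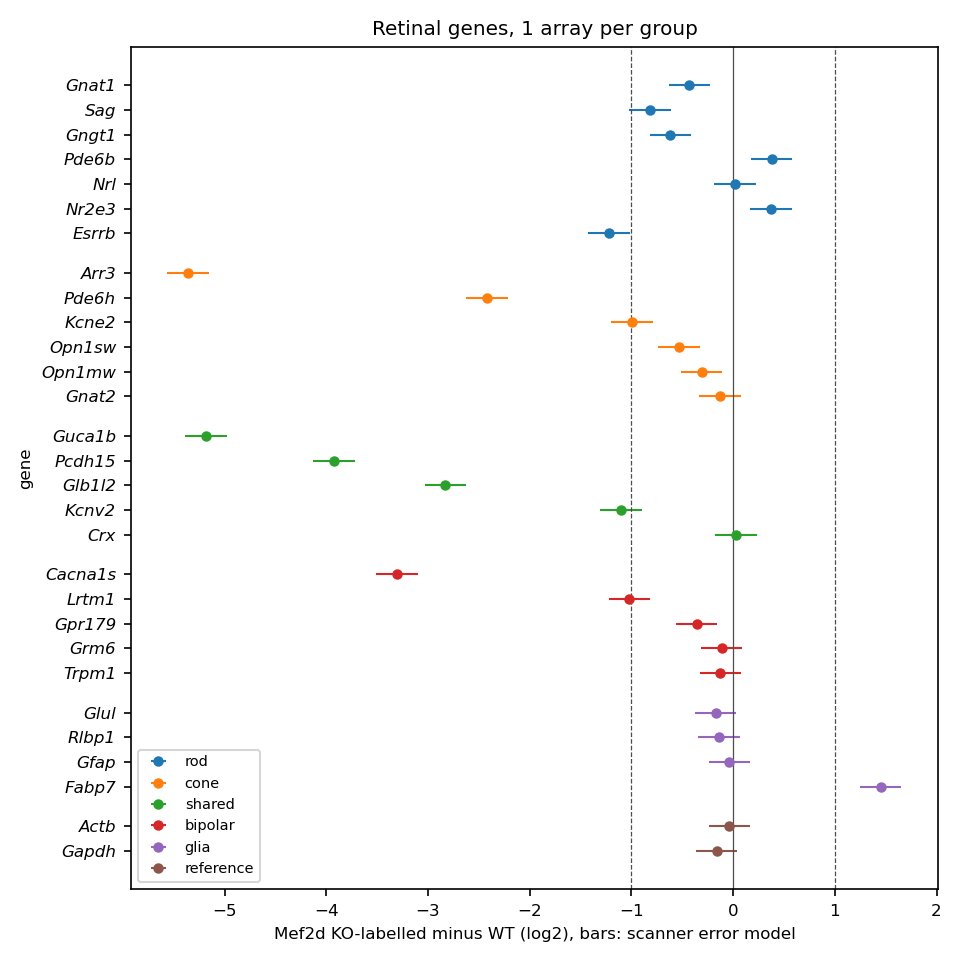
Log2 differences (array labelled Mef2d KO minus WT) of named rod, cone, shared photoreceptor, bipolar, glial and reference genes, with bars for the scanner error model and dashed lines at 2-fold. Arr3 (-5.36) and Guca1b (-5.18) lie far below Gnat1 (-0.43) and Crx (0.028).

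Most bipolar cell genes had small negative differences. Of 32 measured bipolar markers 28 had a negative difference, against 17 with median scaling, with 1, Lrtm1 (-1.02, and -0.84 with median scaling), past 2-fold. Sebox differed by -0.90 and Tpbg by -0.68. The list median of -0.20 (-0.021 with median scaling) lay below those of the 10000 random lists. In the ON bipolar signalling list, 1 of 17 measured genes, Cacna1s, passed 2-fold. Gpr179 differed by -0.36, Gng13 by -0.45 and Pcp2 by -0.34. Grm6 (-0.11), Trpm1 (-0.13) and Prkca (-0.16) had positive differences of 0.066, 0.052 and 0.023 with median scaling. The list median was -0.12 at percentile 0.24, and -0.068 at percentile 12.1 without genes of other lists.

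Other retinal cell types gave small medians. Of 29 Mueller glia markers, Fabp7, a fatty acid binding protein, was at least 2-fold higher (1.45), and Car2 differed by -0.44, Glul by -0.17 and Rlbp1 by -0.14, the last 2 turning to 0.0069 and 0.041 with median scaling. The list median of -0.13 stood at percentile 0.01. Of 31 amacrine markers, Cck (-1.71) was at least 2-fold lower and the median of -0.062 stood at percentile 2.10, or -0.046 at percentile 3.96 with normexp background. The 28 ganglion cell markers stayed within 2-fold (median -0.0059, percentile 25.3), and the 15 horizontal cell markers had a median of -0.17 at percentile 3.35, and of -0.15 at percentile 0.62 with quantile normalization and -0.16 at percentile 0.45 with cyclic loess, both called lower. Glial stress genes had a median of -0.019 at percentile 66.6, which turned to 0.10 at percentile 95.2 with quantile normalization and to 0.13 at percentile 98.7, called higher, with cyclic loess. Of the 27 measured glial stress genes 15 had a negative difference, against 7 with median scaling. Among the 27, Gfap differed by -0.036 (0.14 with median scaling), Nupr1 by -1.73 and Mt2 by 0.65. Edn2 was at least 3.08-fold lower by its bound (difference -0.45 with normexp background). Cxcl10 was higher by a log2 bound of at least 0.59 (difference 0.204 with normexp background). With median scaling the medians of the lists called lower for cone, shared photoreceptor, ON bipolar, Mueller glia and amacrine genes turned positive. So did those of the uncalled rod, synapse, ganglion cell (0.17), horizontal cell (0.013), glial stress (0.16), astrocyte and oligodendrocyte and immediate early lists, while all percentiles stayed as given.

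Lens genes were the list furthest from its random lists. Of 28 measured lens and cornea markers, 14 read on both arrays were at least 2-fold lower and 2 at least 2-fold higher. Lim2 was at least 6.60-fold lower by its bound (difference -1.08 with normexp background). Besides Mip, the crystallin genes Crygn and Crybb2 (-2.64) were among the lower ones. The gene Lgsn differed by 1.62 (1.03 with normexp background) and Crygf by 1.47, the 2 higher ones. The list median was -1.42 and lay below those of the 10000 random lists, and it was -0.58 with normexp background. Of 19 skeletal muscle genes, 3 read on both arrays were at least 2-fold lower, among them Tnnt1, a slow troponin (-2.04), and Pygm, the muscle glycogen phosphorylase (-1.98). The muscle median of -0.48 stood at percentile 1.48, and it was -0.22 with quantile normalization.

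Vascular and immune markers had medians of opposite sign. Of 30 vascular markers 26 had a negative difference, against 17 with median scaling, and Vtn, the gene of vitronectin, was at least 2-fold lower (-2.79 ± 0.20). Its WT level of 5.59 was far above those of Col4a2 (1.77), Sox17 (-1.82) and Sox18 (-1.57). Which cells expressed Vtn was not tested, so its decrease is not shown to be a vascular one. Col4a2 differed by -0.55, Sox17 by -0.48 and Sox18 by -0.46, and the median of -0.22 (-0.044 with median scaling) lay below those of the 10000 random lists. Of 25 microglia markers 2 were at least 2-fold higher, Cd74, the invariant chain of MHC class II (1.77), and Ly86 (1.64). Fcgr3 differed by 0.71 and Ctss by 0.55, and the median was 0.31, above those of the random lists. Blood and leukocyte markers had a median of 0.21, with Hbb-b2 at 0.49 and Cd52 at 0.50. The dim Cd79a differed by -0.73 (-0.32 with cyclic loess and -0.30 with normexp background). Cd3g was at least 1.31-fold lower by its bound. The blood and leukocyte median lay above those of the random lists, and with normexp background it was 0.035 at percentile 97.0. RPE and choroid markers, such as Tyrp1 (0.41) and Slc16a8 (0.39), had a median of 0.13 at percentile 99.7. Astrocyte and oligodendrocyte markers had a median of -0.089 at percentile 16.3.

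Metabolic and stress genes were examined last. Of 22 measured glycolysis genes 20 had a negative difference, against 16 with median scaling, and 1, Hk2, passed 2-fold. Slc16a3, a lactate transporter, differed by -0.53, Pkm by -0.45 and Eno1 by -0.39, and the median of -0.21 (-0.033 with median scaling) lay below those of the 10000 random lists. No member of the unfolded protein response list passed 2-fold, and 2 of 20 had a negative difference. Atf3 differed by 0.84, Atf4, the transcription factor of the integrated stress response, by 0.59 and Vldlr by -0.77, and the median of 0.23 lay above those of the random lists. Of 23 interferon response genes, Irf7 was at least 2-fold lower (-2.40, and -1.45 with normexp background) while the median was 0.13 at percentile 99.98, and 0.00088 at percentile 95.8 with normexp background. Among 24 immediate early genes, Egr1 was higher (1.53) and Fos lower (-1.09, and -0.92 with median scaling), with a median of -0.071 at percentile 11.0, or -0.092 at percentile 1.29, called lower, with quantile normalization. The medians of the apoptosis and p53 targets (0.039, percentile 89.6, and -0.023 with normexp background), of the cell cycle genes (0.021, percentile 88.0) and of the reference genes (0.036, percentile 74.6) were not called. Actb differed by -0.037 (0.14 with median scaling) and Gapdh by -0.16 (0.015 with median scaling).

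**Figure D3:**
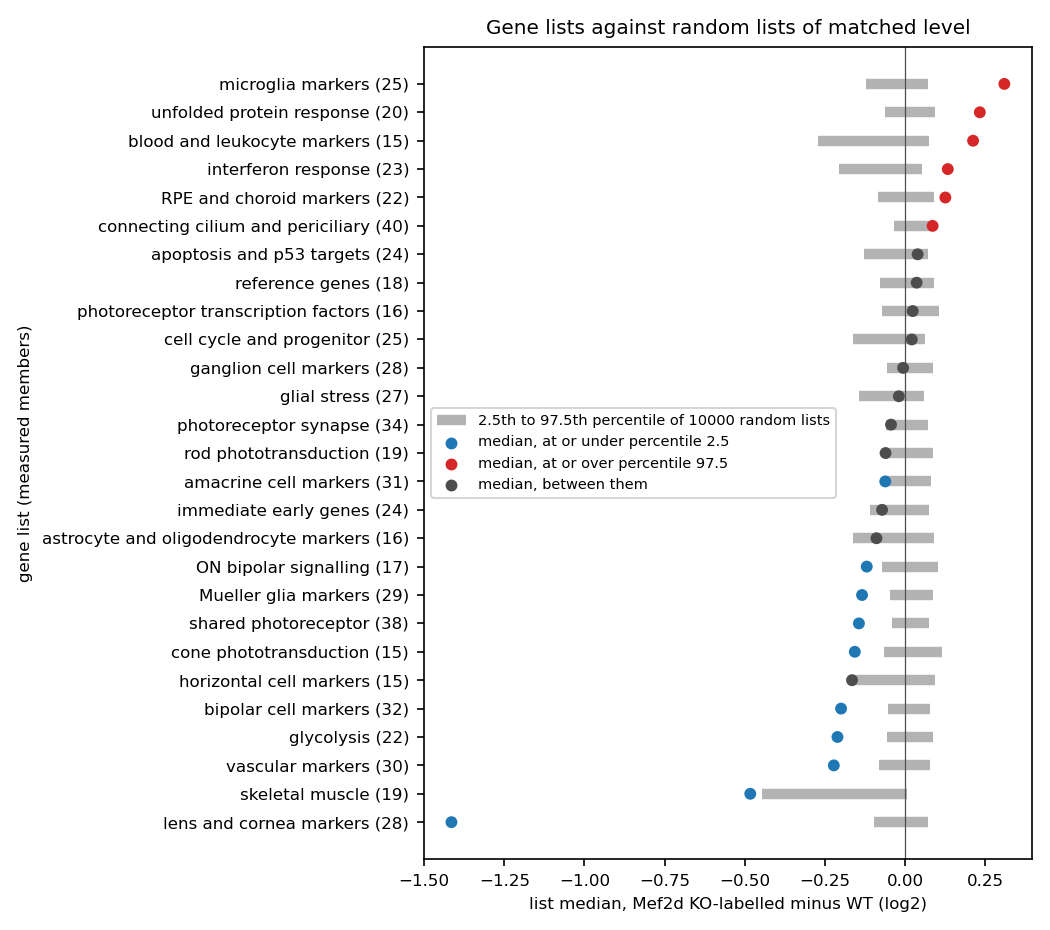
Median log2 difference (array labelled Mef2d KO minus WT) of the measured members of 27 gene lists, with grey bars for the range of 10000 random lists matched on level between the limits used for calls. The lens and cornea list lies at -1.42, and the microglia list at 0.31 is the highest.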

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

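The 5 probes that the scanner files name XIST, which have no RefSeq match and enter no gene count, were all higher on the array labelled Mef2d KO. The 2 of them well above background on both arrays differed by 8.58 and 8.77, and the other 3, not well above background in WT, by at least 6.96, 7.66 and 8.18, so that the median is at least 8.18. They were flagged as a signal in probes the comparisons do not use. The probe A_55_P2137023, with no gene symbol here, was flagged for the same reason, with the largest increase outside XIST among the unnamed probes well above background on both arrays, a difference of 3.59 (12.1-fold). The limit to probes read on both arrays was set after the values were seen. Of the 16374 unnamed probes so read, 507 were at least 2-fold lower and 59 at least 2-fold higher.

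The tests in the rest of this part were chosen after the result was seen. More 2-fold lower than higher genes at or below level -3 (164 against 23) is the first pattern. A weaker response of the array labelled Mef2d KO at low signal may account for it, since a spiked-in control at level -4.56 gave a median of -0.74 (SD 0.25 over 34 spots). The scanner software's background subtraction stays open, because normexp left 12 lower and 2 higher genes there, and its offset shrinks differences in both directions. Cyclic loess, which removes a trend with level, left 51 lower and 68 higher genes there. It centres the differences at every level, so it would remove a one-sided excess of any cause and does not tell the causes apart. Loss of Mef2d is the biological explanation the design gives for dim genes that stay lower, and it was not tested separately.

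The lower lens and cornea list is the second pattern. Cyclic loess, which removes a trend with level, left the list median at -1.14, below those of the random lists, which argues against the low-signal trend as the whole cause. Lens tissue carried over in unequal amounts stays open, since 61.1% of the 18 members above level 0 in WT were at least 2-fold lower, short of nearly all of them. The 6 gamma-A to F crystallins, a set chosen after their values were seen, had a median of 0.072 and none was 2-fold lower. An effect of genotype on crystallin genes is open and cannot be told apart from carry-over with 1 array per group.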

How the results depend on the processing

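Leaving out a replicate was not possible with 1 array per group. No paired analysis was possible because each group has 1 array. The differences of Mef2d, of both probes, stayed positive under the 6 scaling, background and source alternatives. The 281 genes at least 2-fold lower became 170 with median scaling, 164 with quantile normalization, 162 with cyclic loess and 103 with normexp background. They became 893 with genes well above background on at least 1 array, 1739 with no filter, and 184 when the brighter array also had to reach 4 times the lowest signal well above background. The 100 higher genes became 151, 157, 154 and 61 with those same 4 scaling and background choices and 225 with no filter. The 44 genes at least 4-fold lower became 29 with normexp, 201 with the filter on 1 array and 310 with none, and the 15 higher ones became 5 with normexp and 25 with no filter. Bounds of at least 2-fold lower (176) became 96 with median scaling, 32 with quantile normalization, 45 with cyclic loess and 7 with normexp, and higher ones (6) became 57 with quantile normalization, 24 with cyclic loess and 1 with normexp. The filters change which genes are counted by construction, and for the other settings the cause was not tested.

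With median scaling, which moves the median of all genes to 0.17, medians of lists called lower turned positive for cone (0.021), shared photoreceptor (0.034), ON bipolar (0.059), Mueller glia (0.044) and amacrine genes (0.12), at unmoved percentiles. Medians of uncalled lists turned positive for rod (0.12), synapse (0.13), ganglion cell (0.17), horizontal cell (0.013), glial stress (0.16), astrocyte and oligodendrocyte (0.089) and immediate early genes (0.11). Normexp turned ganglion cell genes to 0.0082 and apoptosis genes to -0.023, and the mean over a gene's probes turned ganglion cell genes to 0.00037, none of them called. Glial stress turned to 0.10 with quantile normalization and to 0.13 with cyclic loess, and with the latter was called higher. Calls ended with normexp for connecting cilium (0.052), amacrine (-0.046), blood (0.035) and interferon genes (0.00088), for ON bipolar genes without genes of other lists (-0.068), and for amacrine genes without their largest difference (-0.060). The rod list was called lower without genes of other lists (-0.091) and with 10 bins (-0.061). Horizontal cell genes were called lower with quantile normalization (-0.15), cyclic loess (-0.16), members on both arrays (-0.16), without their largest difference (-0.16) and without genes of other lists (-0.20). Immediate early genes were called lower with quantile normalization (-0.092), members on both arrays (-0.12) and without their largest difference (-0.12). In all, 355 of 378 list alternatives kept the call. Of 1155 named gene alternatives, 1123 kept their side of 2-fold, with none changing sign once called. Part of these tallies was fixed in advance. Median scaling, and the percentile over probes well above background on both arrays, add the same constant to every difference. A list's percentile then cannot move, and only the sign of its median can. The series table is nearly the same case. Genes named as largest decreases or increases had to pass 2-fold with normexp and quantile normalization, so they could not change side there.

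Chosen after seeing the data, a mean level above -3 left 117 genes at least 2-fold lower and 77 higher, and leaving out X and Y genes left 269 and 99. Without those chromosomes the horizontal cell list was called lower (-0.16). Setting list members read on 1 array to their bound changed no call.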

Other observations

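The tests of chromosome neighbours were written before their results were seen. Genes carried with the targeted allele from another strain could differ near Mef2d on chromosome 3. Of the 200 measured genes nearest to Mef2d, 1% were at least 2-fold apart with cyclic loess values, against a median of 2% over windows of 200 autosomal genes, so linked genetic background around Mef2d was not seen as a source of the differences. Linked genetic background on other chromosomes stays open. With cyclic loess values, the fullest window of 50 neighbouring genes held 5 genes at least 2-fold higher. The fullest windows of shuffled gene orders had a median of 4, a margin short of the one set in advance. Windows holding 5 lay on chromosome 2, with Kcng1 and Tshz2, and on chromosome 10, with Gli1 (0.94 in the main values) and Shmt2. These genes were named after their values were seen. Loss of Mef2d and the sex of the animals, by the Xist values, are untested explanations for these genes.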
